A study of Mus musculus with 2 samples.

How the data were processed

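Single cells were prepared from fresh mouse hearts of 2 genotypes, C57/B6 wild type and AC8 overexpressing. AC8 is adenylyl cyclase 8, an enzyme that makes the second messenger cyclic AMP. Per the labels, the mice of each genotype were pooled, cells were sorted by CD45 and CD31 into leukocytes, mesenchymal cells and endothelial cells, and the 3 fractions were mixed in equal numbers. Each mixture gave 1 droplet library with the 10x Genomics system, sequenced on an Illumina NovaSeq instrument. Neither the number of mice per pool nor perfusion or lysis of red cells is described in the labels. The deposited values are counts, whole numbers of unique molecular identifiers (UMIs) per gene and cell, which the authors generated with Cell Ranger per the labels' protocols. The genome build, mm10, comes from the submitters' processing notes, and the Cell Ranger version is not given in the sources used here. No filter on cells or genes by the authors is described in the labels, and the lowest UMI total of a deposited cell was 500 in both libraries. Both matrices list the same 22441 gene symbols, of which 16386 had a UMI. Gene positions and lengths were taken from GENCODE vM21 on GRCm38, which is the assembly called mm10, by matching symbols, and 22039 (98.2%) matched.

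Cells were kept with at least 1000 UMIs, at least 500 genes and at most 10% of UMIs from mitochondrially encoded genes. In the wild-type library 2066 of 5800 cells (35.6%) and in the AC8 library 1126 of 4867 cells (23.1%) were under the minimum of UMIs or genes, and 53 and 85 were over the mitochondrial limit. Doublets were scored within each library as the share of simulated doublets among a cell's nearest neighbours. The top-scoring share given by a loading rate of 0.8% per 1000 cells was removed, which took 173 of 3719 and 145 of 3723 cells. Counts were scaled to 10000 per cell and logged. The 2000 most variable genes, ranked within each library by the variance of negative binomial residuals, were reduced to 30 principal components over both libraries together, without integration. A shared-neighbour graph with 15 neighbours per cell was partitioned with the Leiden algorithm at a resolution of 1. The work used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, leidenalg 0.10.2, igraph 0.11.9 and matplotlib 3.10.9.

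A cluster took the cell type whose fixed markers stood highest in it, and is called "like" that type throughout. At least 3 markers had to be detected in at least 10% of its cells. A cluster stayed unnamed where a type of another lineage scored at least 0.75 times as high, or where its 10 leading genes held more markers of another type than of its own. The markers were fixed before the data were examined. The scoring rule was set afterwards, and its comparison of leading genes with clusters of other types, rather than with every other cluster, was a refinement made after a first look at the clusters. The rule left 1 cluster unnamed, with leading genes of macrophages beside the T cell genes Tcf7 and Lef1. Within each gate, the share of each class was taken over that gate's named cells, because the mixing of the sorted fractions sets the shares of the 3 gates themselves.

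For each class with at least 100 kept cells in each library, raw counts were summed per library and divided by the class's total and scaled to counts per 1000000 (CPM). Log2 ratios of AC8 over wild type used a pseudocount of 10 CPM, while folds are plain ratios of CPM with an exact interval. With 1 library per genotype no test was possible, and no p-value, standard error or number of changed genes was computed. Intervals are exact at 95%, Poisson for CPM, its binomial form for ratios and Clopper-Pearson for shares. Intervals for differences of shares combine the limits of both shares. All of them cover counting error only, not differences between cells, animals or preparations. Those for CPM and ratios treat UMIs as independent, although the UMIs of a gene can lie in few cells.

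The genes named first for each class followed a fixed rule. A gene needed at least 30 summed UMIs, at least 100 CPM in the higher library, and a level there of at least 20% of its highest class in that library. The last was meant to keep free RNA of another class from being named, but it does not exclude it. Mitochondrially encoded, ribosomal protein, hemoglobin, sex and antigen receptor segment genes and unnamed gene models were left out. The 8 highest and 8 lowest log2 ratios were taken in the 3 classes with the most cells and 4 of each in the fourth. Of each fixed list, the 2 to 4 measured members with the largest ratios, and any member at least 2-fold apart, were open to be named. Adcy8, Rela, Pecam1, Ptprc and the sex genes were always to be given, but Xist is not among the gene symbols of the matrices and could not be.

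The 34 gene lists were fixed as well. The 5 main lists, chosen for the NF-kB and inflammation themes of the series title, were NF-kB target genes, type I interferon response, MHC class II presentation, chemokines and cytokines, and fibroblast activation. Members needed at least 20 summed UMIs in the class, and a list at least 5 such members. A list's value is the median log2 ratio of its members, set beside its percentile among 10000 random lists of the same size matched on mean CPM in 20 bins. A list is said to stand apart at a percentile of at most 2.5 or at least 97.5, as a description of these 2 libraries. The 4 classes gave 110 list values, of which 41 stood apart. Shares of cells with a UMI were taken after thinning each cell to 1000 UMIs, which every kept cell reached.

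The ratio, interval and list steps were tested on simulated data, with Poisson counts drawn from each class's own means and 200 genes changed 2-fold. The intervals held the true ratio for 190 of them in the fibroblast simulation (11114 genes), 191 in the macrophage simulation (9034 genes), 192 in the endothelial simulation (8257 genes) and 189 in the B cell simulation (4050 genes). Of 200 unchanged lists, 12, 11, 12 and 13 stood apart in the same order, and 20 of 20 lists raised 1.5-fold were found in each. The draws followed the model that the intervals assume, without UMIs clumped in single cells or genes that move together. They therefore check the steps and not their error rate in these data. The pseudocount drew the ratios toward 0, with a median log2 ratio of 0.71, 0.83, 0.77 and 0.90 for genes raised 2-fold.

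The cell filter, clustering settings, markers, lists, rule for named genes and a first set of alternative settings were chosen before the data were examined. That set held other mitochondrial limits, no doublet removal, other clustering settings, each library clustered alone, a stricter minimum of UMIs and genes, other pseudocounts and scalings, thinned cells, other gene minimums, the mean over list members, and lists without members of the stress list. Alternatives added after seeing the data were all deposited cells, another random seed, random lists matched on gene length too, macrophage-like cells without 1 cluster, and the largest capillary endothelial cluster alone. The minimum of 1000 UMIs was fixed before it was known that the deposited cells began at 500, so shares are also given over all deposited cells. For classes, that setting dropped the minimums of UMIs and genes but kept the mitochondrial limit and doublet removal.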

Results

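Droplet single-cell RNA sequencing compared heart cells of wild-type mice with those of mice that overexpressed AC8, in cardiomyocytes according to the series title. The question set by that title was whether the change in cardiomyocytes is accompanied by NF-kB (RelA) activity and inflammation in the other cells of the heart. The wild-type library held 5800 cells with 9664932 UMIs, a median of 1344 per cell, and the AC8 library 4867 cells with 11076564 UMIs, a median of 1832. After filtering, 3546 wild-type cells with a median of 1884.5 UMIs and 3578 AC8 cells with a median of 2324.5 UMIs were kept. They formed 21 clusters, of which 20 fell into 10 classes. The unnamed cluster, which carried macrophage and T cell genes together, had 37 wild-type and 26 AC8 cells. Each genotype had 1 library of pooled mice, so no difference has a replicate check and none was tested. In what follows, paired values in parentheses are wild type first and AC8 second.

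Adcy8, which encodes AC8 (chromosome 15, 64697084 to 64922296, minus strand, GRCm38), had 0 UMIs among the kept cells of both libraries, which allows up to 0.401 CPM in wild type and 0.314 CPM in AC8. Over all deposited cells it had 0 and 1 UMIs. Cardiomyocytes were not sorted and a transgene need not map to the mouse gene, so this count does not check the genotype labels. Rela, which encodes the p65 subunit of NF-kB (chromosome 19, 5637483 to 5648130, plus strand), stood at 76.5 CPM (95% interval 70.3 to 83.0) in wild type and 85.0 CPM (79.3 to 91.1) in AC8. Its levels were 76.2 and 79.0 CPM in fibroblast-like cells, 81.3 and 88.2 in macrophage-like cells, 70.4 and 89.7 in B cell-like cells, and 79.3 and 109 in endothelial-like cells. The counting interval of that last ratio, 1.38, lay just above 1. Pecam1, which encodes the endothelial adhesion molecule CD31, stood at 1155 and 1174 CPM in endothelial-like cells and at 19.3 and 13.8 CPM in fibroblast-like cells. Ptprc, which encodes the leukocyte antigen CD45, was lower in AC8 macrophage-like cells (473 and 326 CPM), at 521 and 482 CPM in B cell-like cells, and at 6.43 and 3.84 CPM in fibroblast-like cells. The Y-linked genes Ddx3y (524 and 522 UMIs), Uty (99 and 119), Kdm5d (121 and 122) and Eif2s3y (358 and 456) were detected in both pools.

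B cell-like cells, recognised by the B cell receptor genes Cd79a and Cd79b and by Ms4a1, made up 107 of 891 leukocytes in wild type (12.0%, 9.95 to 14.3) and 297 of 1344 in AC8 (22.1%, 19.9 to 24.4), a difference of 10.1 percentage points (6.90 to 13.2). Macrophage-like cells, marked by the complement genes C1qa, C1qb and C1qc, were the larger class in both and took a smaller share in AC8, 553 cells (62.1%, 58.8 to 65.3) against 705 (52.5%, 49.7 to 55.2), a difference of -9.61 points (-13.8 to -5.36). Dendritic cell-like cells, led by Cd209a, Ccl22 and Ccl17, were 6.85% (5.28 to 8.71) and 9.38% (7.87 to 11.1). NK cell-like cells, led by the granzyme gene Gzma, were 4.04% (2.85 to 5.55) and 2.16% (1.45 to 3.08). Neutrophil-like cells were 4.94% (3.61 to 6.57) and 5.80% (4.61 to 7.19), in a cluster led by S100a8, S100a9 and Retnlg but also by the monocyte genes Plac8 and Chil3. It also held the monocyte markers Ly6c2 (1110 and 601 CPM), Csf1r (504 and 567) and Ccr2 (339 and 421), beside the neutrophil marker Csf3r (206 and 118). At a Leiden resolution of 1.6 the neutrophil-like share was 1.69% and 0.89%, and without doublet removal 1.68% and 1.02%. T cell-like cells were 10.1% (8.20 to 12.3) and 8.11% (6.71 to 9.70). For neutrophil-like and T cell-like cells the interval of the difference included 0. Among mesenchymal cells the fibroblast-like share was 94.2% and 94.0%, the mural-like share 4.07% and 4.63%, and the Schwann-like share 1.74% and 1.40%.

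The minimum of 1000 UMIs fell unevenly on the classes. Over all deposited cells, with the mitochondrial limit and doublet removal still applied, it left out 72.4% of B cell-like cells in wild type and 46.5% in AC8. The shares left out were 66.0% and 46.8% of endothelial-like, 67.5% and 34.5% of mural-like, and 17.0% and 9.43% of macrophage-like cells. The 51 and 32 cells called neutrophil-like there were mostly under it too (90.2% and 81.3%), so they were largely other cells than the kept neutrophil-like class. Over all deposited cells the B cell-like share was 355 of 1355 leukocytes (26.2%, 23.9 to 28.6) in wild type and 546 of 1717 (31.8%, 29.6 to 34.1) in AC8, and the macrophage-like difference was -2.12 points. With at least 2000 UMIs and 1000 genes per cell the macrophage-like difference turned to 5.23 points and the B cell-like one to -0.67 points. Among all deposited cells with at least 2000 UMIs, B cell-like cells were 3 of 342 and 10 of 757 leukocytes. That was a difference of 0.44 points (-1.36 to 1.74), so the B cell-like direction at this depth was not clear. The leukocyte, mesenchymal and endothelial gates held 25.1%, 56.8% and 17.0% of kept wild-type cells and 37.6%, 45.9% and 15.8% of kept AC8 cells, which the mixing of sorted fractions and the minimum of UMIs both set.

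**Figure D1:**
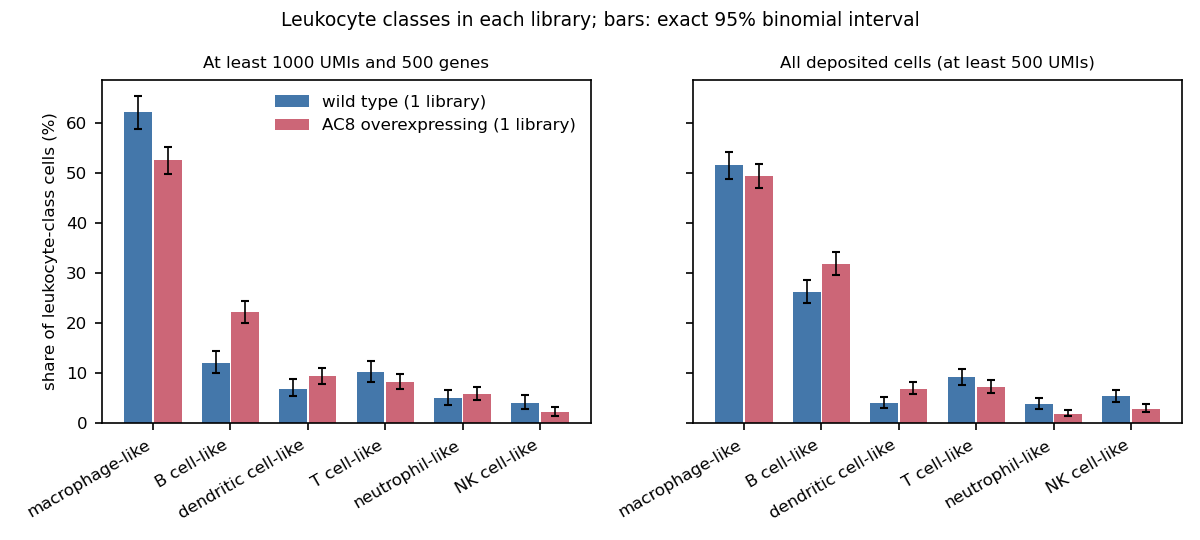
Share of each leukocyte class (percent of leukocyte-class cells, vertical axis) in the wild-type and AC8 libraries, among kept cells on the left and all deposited cells on the right, with exact 95% binomial intervals that cover counting error only. The mitochondrial limit and doublet removal applied on both sides. The B cell-like share was 12.0% and 22.1% among kept cells and 26.2% and 31.8% among all deposited cells.

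In macrophage-like cells the genes with the highest ratios in AC8 were Gpnmb, Spp1, Lgals3, Mmp12, Ccl8, Il1rn, Ctsd and Cd9. Gpnmb, a lysosomal membrane glycoprotein (chromosome 6, 49036546 to 49070929, plus strand), was 13.8-fold higher (9.28 to 21.5; 20.3 and 281 CPM). Spp1, which encodes the secreted matrix protein osteopontin (chromosome 5, 104435118 to 104441050, plus strand), was 8.05-fold higher (6.69 to 9.77; 96.8 and 779 CPM). Mmp12, macrophage elastase, was 7.24-fold higher (5.71 to 9.30), and Lgals3, the lectin galectin-3, 6.63-fold (6.02 to 7.31; 365 and 2419 CPM). Il1rn, the interleukin-1 receptor antagonist, was 5.60-fold higher (4.16 to 7.72) and Ccl8, a monocyte-attracting chemokine, 5.28-fold (4.20 to 6.70). Ctsd, a lysosomal protease (332 and 1247 CPM), and Cd9, a tetraspanin (138 and 510 CPM), completed the 8. Cd9 stood higher still in AC8 fibroblast-like cells, at 1135 CPM. The lowest ratios were those of Mmp13, a collagenase (160 and 43.3 CPM), the heat shock genes Hsph1 (154 and 52.9) and Hspa1b (2051 and 867), Dennd4a (274 and 103), Casp4, an inflammatory caspase (210 and 79.4), Cmah (109 and 42.5), Nufip2 (122 and 48.9) and Ednrb, an endothelin receptor (204 and 87.8). The counting interval of the ratio excluded 1 for all 16 genes. As they were picked by their ratios from the same counts, this is no separate support.

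Gpnmb had UMIs in 5 wild-type and 54 AC8 macrophage-like cells and Spp1 in 13 and 118. The counting intervals of these genes treat their UMIs as independent and leave out this spread between cells. At an equal depth of 1000 UMIs, Spp1 was detected in 1.99% and 10.4% of macrophage-like cells and in 0.00% and 0.32% of fibroblast-like cells, and Lgals3 in 15.6% and 39.6% against 0.53% and 1.36%. For Gpnmb the shares were 0.36% and 4.26% of macrophage-like against 2.05% and 2.98% of fibroblast-like cells, and Cd9 was more frequent in fibroblast-like (44.3% and 58.5%) than in macrophage-like cells (25.5% in AC8). Before thinning, macrophage-like shares were 2.35% and 16.7% for Spp1 and 26.0% and 59.0% for Lgals3. The median depth of those cells was 1938 and 3012 UMIs in macrophage-like and 2161 and 2744 in fibroblast-like cells. When the cells were clustered with 17 genes that led the Spp1 and Gpnmb cluster or were named above left out, 1 cluster still gathered 130 of its 164 cells, and it held 13 of the 555 wild-type (2.34%) and 120 of the 705 AC8 cells (17.0%) then called macrophage-like, shares whose counting intervals did not overlap. Outside the original Spp1 and Gpnmb cluster, in 539 and 555 cells, Gpnmb had 0 and 2 UMIs, while Ccl8 (70.2 and 514 CPM), Lgals3 (206 and 447), Il1rn (25.7 and 70.5), Mmp12 (26.5 and 66.8), Spp1 (10.3 and 25.7), Cd9 (120 and 239) and Ctsd (249 and 473) were higher in AC8.

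**Figure D2:**
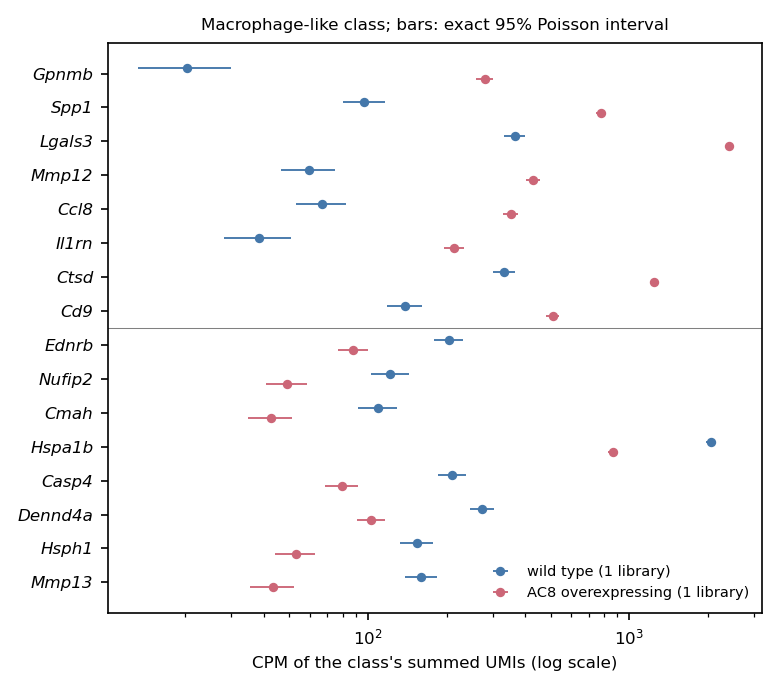
Level (CPM, log axis) of the 16 genes named by rule in macrophage-like cells of the wild-type and AC8 libraries, with exact 95% Poisson intervals that cover counting error only. Gpnmb stood at 20.3 and 281 CPM and Mmp13 at 160 and 43.3 CPM.

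Type I interferon response genes were higher in AC8 macrophage-like cells, 25 of 37 measured members, with a median log2 ratio of 0.39 at percentile 100 of random lists. They included Irf7, the transcription factor that amplifies interferon production (39.8 and 152 CPM), the antiviral effectors Ifit3 (17.9 and 74.2) and Oasl1 (5.69 and 30.5), and the ubiquitin-like modifier Isg15 (55.3 and 150). MHC class II presentation genes were lower, 8 of 10 members, with a median of -0.36 at percentile 1.51. Among them were Ciita, the master regulator of the class (51.2 and 22.5 CPM), and the antigen-presenting chains H2-Aa (7218 and 5037) and H2-Ab1 (5052 and 3623), while Ctss, a protease of the same pathway, was higher (1576 and 2522). The mean over members of this list, -0.26, did not stand apart (percentile 3.91). In the largest macrophage-like cluster the list was at -0.15 (percentile 16.9), and in the cluster led by Lyve1 at -0.61 (percentile 0.00). NF-kB target genes did not stand apart (21 of 39 higher, median 0.05, percentile 70.3), with Ptgs2, an inducible cyclooxygenase, higher (24.4 and 53.3 CPM), Il6, a proinflammatory cytokine, lower (15.5 and 2.81), and Birc3, an apoptosis inhibitor, lower (229 and 129). Outside the Spp1 and Gpnmb cluster Ccl5, a chemokine gene of the same list, was 6.58-fold higher (3.92 to 11.8; 13.7 and 90.1 CPM). Ccl5 was also a leading gene of the NK cell-like cluster. Chemokines and cytokines did not stand apart either (22 of 32 higher, median 0.06, percentile 76.7), although they did as a mean over members (0.30, percentile 100) and in the largest macrophage-like cluster (0.24, percentile 98.6).

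Recruited monocyte genes were higher in AC8 macrophage-like cells, 13 of 18 members (median 0.53, percentile 100), among them Fn1, fibronectin (60.2 and 220 CPM), F10, coagulation factor X (4.88 and 44.1), and the calcium-binding protein gene S100a6 (351 and 858). Without the Spp1 and Gpnmb cluster the median was 0.18 and no longer stood apart (percentile 92.3). The fibroblast activation list stood apart in this class as well (5 of 8 higher, median 0.43, percentile 99.5), with Fn1 higher, whereas Acta2 (4.88 and 21.7 CPM) and Timp1 (1.63 and 10.8 CPM) were at most 3.22% of their level in the highest class. That call ended without doublet removal, where the median was 0.00 (percentile 30.6), and over all deposited cells the median was -0.13. Neutrophil genes were lower (8 of 9, median -0.41, percentile 1.13), including the cytokine genes Il1b (1177 and 770 CPM) and Ccl3 (490 and 320). Angiogenesis genes (10 of 12 lower, median -0.38, percentile 0.57), collagens (6 of 8 lower, median -0.31, percentile 1.62) and venous and endocardial genes (4 of 5 lower, median -0.64, percentile 0.25) were also lower. Several members are genes of other classes, such as Col3a1 (20.3 and 9.62 CPM) and Mgp (38.2 and 20.9), which stood at no more than 0.769% of their level in the highest class and are not read as macrophage expression. Those calls depended on the settings. Without the Spp1 and Gpnmb cluster the collagen median was -0.08 (percentile 22.3) and the venous and endocardial one -0.09 (percentile 33.2), and the neutrophil list lay at percentile 3.23 with a pseudocount of 1 CPM. Technical lists moved in this class too: dissociation stress genes were lower in AC8 (22 of 31, median -0.33, percentile 0.01), as were mitochondrially encoded genes (12 of 13, median -0.69, percentile 0.00) and ribosomal protein genes (51 of 81, median -0.17, percentile 0.14).

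In fibroblast-like cells, 1898 in wild type and 1543 in AC8, the genes with the highest ratios in AC8 included Timp1, C4b and Serpina3n and a pair of interferon-induced genes. Timp1, an inhibitor of matrix metalloproteinases (chromosome X, 20870166 to 20874735, plus strand), was 2.88-fold higher (2.61 to 3.20; 117 and 336 CPM), C4b, complement component 4, 2.84-fold (2.37 to 3.41; 37.9 and 107 CPM), and Serpina3n, an acute-phase protease inhibitor, 2.26-fold (2.03 to 2.51; 114 and 258 CPM). Ifi27l2a (chromosome 12, 103442167 to 103443680, minus strand; 1370 and 2991 CPM) and Isg15 (70.9 and 163 CPM), both interferon-induced, were 2.18-fold (2.12 to 2.25) and 2.30-fold higher (2.01 to 2.64). The list was completed by Nmt1, an N-myristoyltransferase (63.4 and 135 CPM), Lmo4, a LIM-only transcriptional regulator (110 and 215), and Ccnb1ip1 (43.4 and 105), which was higher in every class compared. The lowest ratio was that of Thbs1, thrombospondin 1, a matricellular activator of TGF-beta, with 461 and 140 CPM, a ratio of 0.304 (0.278 to 0.333). Matrix components followed, with Smoc2 (940 and 428 CPM), the small proteoglycan gene Ogn (1181 and 632) and the basement membrane gene Nid1 (1047 and 569), besides Ier5 (181 and 86.5), Jmjd1c (132 and 66.4), Wsb1 (110 and 54.9) and Abca6 (104 and 52.6). The counting interval of the ratio excluded 1 for all 16, which were picked by these same ratios.

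Type I interferon response genes were higher in AC8 fibroblast-like cells, 28 of 36 members (median log2 ratio 0.25, percentile 100), with Ifit3 (31.9 and 84.2 CPM) and Irf7 (23.7 and 57.6) beside Isg15 and Ifi27l2a. MHC class I presentation genes were higher as well, 13 of 17 (median 0.27, percentile 99.9), including H2-T22 (67.3 and 107 CPM) and the immunoproteasome gene Psmb8 (80.6 and 112). NF-kB target genes were lower, 21 of 34 (median -0.23, percentile 0.10), among them the chemokine genes Cxcl1 (927 and 525 CPM) and Ccl7 (180 and 98.4) and Ptgs2 (196 and 114). The technical list of dissociation stress genes, which shares no member with it, was lower in the same cells (26 of 31, median -0.22, percentile 0.09). Whether handling had a part in the lower NF-kB targets was not tested. Without doublet removal the NF-kB list no longer stood apart, at -0.07 (percentile 30.8). Within single clusters its median was lower in all 4 measured (-0.13, -0.16, -0.27 and -0.12), but it stood apart only in the third, led by Cilp and Mfap4 (percentile 0.42). The fibroblast activation list was higher, 19 of 31 (median 0.16, percentile 99.6), with Postn, a matrix protein of activated fibroblasts, at 190 and 359 CPM and Cthrc1, a secreted marker of matrix-producing fibroblasts, at 1 and 56 UMIs, against the decrease of Thbs1. By cluster its median was 0.19 and 0.21 in those led by Cxcl14 and by Cilp, and -0.04 and -0.02 in those led by Ccl19 and by Cd248, where it did not stand apart. Chemokines and cytokines were split (17 of 31 higher, median 0.13, percentile 99.8), and among members with at least 100 UMIs the median was -0.01 (percentile 58.8). They stood apart in none of the 4 clusters. The 6 measured MHC class II genes had a median of 0.29 (percentile 99.9), but H2-Ab1 (12.6 and 20.3 CPM) and H2-Eb1 (14.7 and 27.5 CPM) were at no more than 0.306% of their level in the highest class. Of the clusters with enough measured members, the list was higher in that led by Ccl19 (0.85, percentile 100) and not in the largest (-0.03, percentile 57.2).

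Collagen genes were lower in AC8 fibroblast-like cells, 18 of 24 (median -0.27, percentile 0.09), including Col15a1 (1173 and 759 CPM), a basement membrane collagen, and Col6a6 (81.7 and 48.1). Col1a1 was among the members that were higher (1559 and 1723 CPM). Against random lists matched on gene length too, the percentile of the collagen list was 7.95. Angiogenesis genes were lower, 17 of 23 (median -0.18, percentile 1.42, and 3.06 when matched on length), with the angiopoietin receptor gene Tek at 75.5 and 46.5 CPM. Targets of cyclic AMP and its transcription factor CREB were lower in 22 of 23 (median -0.36, percentile 0.01), among them Nr4a3 (102 and 37.2 CPM) and Nr4a2 (46.4 and 23.9), orphan nuclear receptors induced by the pathway, Sik1, a salt-inducible kinase (56.2 and 19.9), and the cyclic AMP phosphodiesterase gene Pde10a (25.3 and 6.77). The list shares 6 members with the dissociation stress list, which was lower too (26 of 31, median -0.22, percentile 0.09), as were mitochondrially encoded genes (9 of 13, median -0.45, percentile 0.00).

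Blood endothelial-like cells, 603 in wild type and 566 in AC8, had higher levels of Ccn3, Clu, Edn1 and Rcan1, among others, in AC8. Ccn3, a matricellular protein, was 3.94-fold higher (2.52 to 6.38; 28.3 and 112 CPM), and Clu, the secreted chaperone clusterin, 2.95-fold (2.41 to 3.62; 148 and 437 CPM). Edn1, which encodes the vasoconstrictor endothelin 1, was 2.60-fold higher (1.80 to 3.82; 46.4 and 121 CPM) and Rcan1, an inhibitor of calcineurin, 2.70-fold (1.84 to 4.02; 43.0 and 116 CPM). Ccnb1ip1 (28.3 and 106), Nts, neurotensin (51.0 and 128), Psmc5, a proteasome subunit (63.4 and 152), and the immediate-early gene Ier3 (485 and 1039) were the others. Timp4, a metalloproteinase inhibitor of cardiac capillaries (chromosome 6, 115241892 to 115252205, minus strand), was 3.63-fold lower in AC8 (2.80 to 4.78; 299 and 82.3 CPM), and Aqp1, a water channel, stood at 0.447 times its wild-type level (0.400 to 0.499; 1162 and 519 CPM). Lower levels were also seen for Id1, a target of BMP signals (922 and 475 CPM), Gja1, which encodes connexin 43 (147 and 72.1), Setd2 (122 and 60.8), Mia3 (116 and 57.5), Oaz2 (149 and 76.6) and Rack1 (361 and 193). The counting interval of the ratio excluded 1 for all 16 genes, which were picked by these same ratios.

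**Figure D3:**
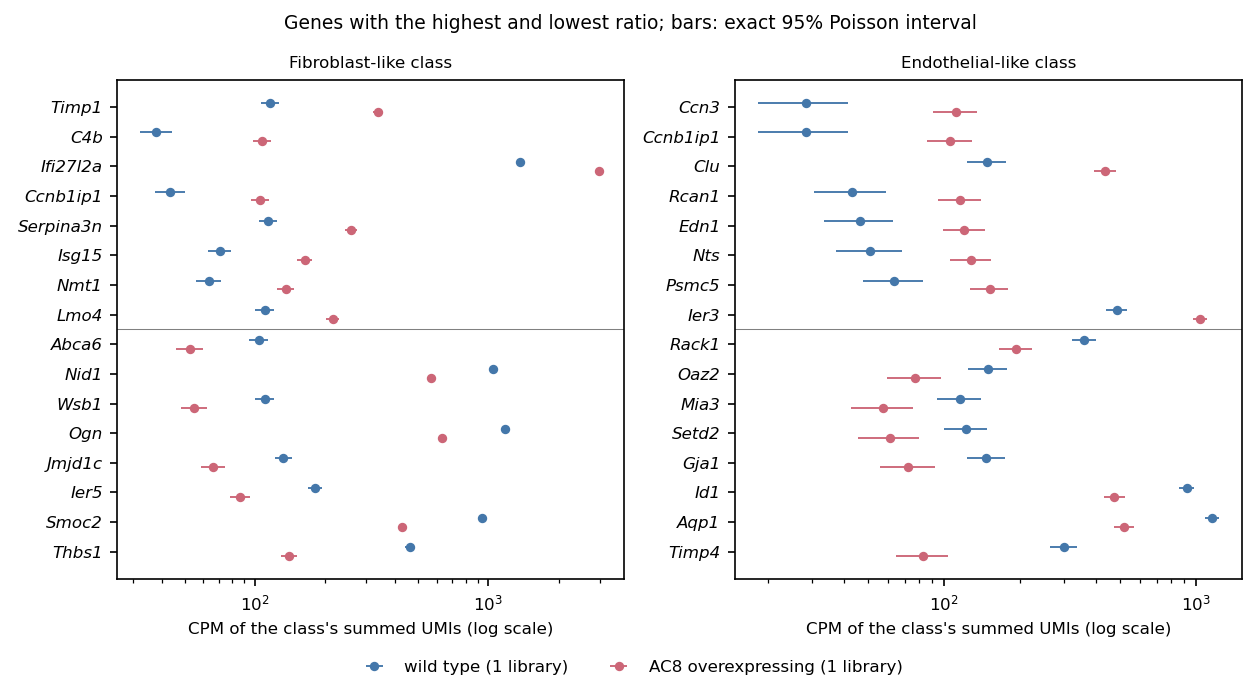
Level (CPM, log axis) of the 16 genes named by rule in fibroblast-like cells on the left and in endothelial-like cells on the right, in the wild-type and AC8 libraries, with exact 95% Poisson intervals that cover counting error only. The upper 8 genes of each panel were higher in AC8, as Timp1 (117 and 336 CPM), and the lower 8 were lower, as Timp4 (299 and 82.3 CPM).

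Angiogenesis genes were lower in AC8 endothelial-like cells, 24 of 28 (median log2 ratio -0.36, percentile 0.00), including the tip cell gene Esm1 (54.4 and 13.5 CPM), the peptide hormone gene Apln (79.3 and 43.9), the VEGF co-receptor gene Nrp2 (293 and 175) and the chemokine receptor gene Cxcr4 (26.1 and 11.3). Arterial genes were higher, 12 of 17 (median 0.27, percentile 99.8), with the connexin gene Gja4 (53.2 and 92.4 CPM), the elastic fibre gene Fbln5 (123 and 204) and the kinase gene Bmx (20.4 and 38.3), while Eln, elastin, was lower (90.6 and 54.1). Over all deposited cells Eln was not lower (log2 ratio 0.07). Capillary genes were lower, 11 of 14 (median -0.23, percentile 1.10), with Gpihbp1, which anchors lipoprotein lipase (1621 and 995 CPM), Rgcc (1297 and 878) and the fatty acid carrier gene Fabp4 (16669 and 11681) next to Timp4. In the largest capillary cluster alone, 456 and 393 cells, the capillary list had a median of -0.12 (percentile 9.97) and the arterial list 0.24 (percentile 98.0). In the arterial cluster the capillary list stood at -0.50 (percentile 0.07) and the arterial list at 0.08 (percentile 67.6). The arterial cluster, of which Clu was a leading gene, held 119 of 603 endothelial-like cells in wild type and 144 of 566 in AC8, which bears on both lists and on Clu. Collagens were lower in 9 of 11 (median -0.31, percentile 1.10, and 6.12 when matched on gene length), but their median was -0.01 over all deposited cells (percentile 47.4) and -0.13 in the capillary cluster alone (percentile 21.8).

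Type I interferon response genes were higher in AC8 endothelial-like cells, 25 of 35 (median 0.17, percentile 99.7), among them Ifi47, an interferon-induced GTPase (38.5 and 87.9 CPM), Ifit3b (24.9 and 59.7) and Isg20, an antiviral exonuclease (18.1 and 42.8). In the arterial cluster the median was -0.22 and did not stand apart (26 members, percentile 10.8). NF-kB target genes did not stand apart (13 of 28 higher, median -0.01, percentile 60.8), with Gadd45b, a stress-induced gene, higher (110 and 234 CPM) and Vcam1, an adhesion molecule for leukocytes, lower (75.9 and 45.1). In the arterial cluster alone, however, these targets were higher in AC8 (14 members, median 0.39, percentile 99.6), as were endothelial activation and adhesion genes (11 members, 0.47, percentile 99.9), but the technical list of dissociation stress genes rose in the same cells (31 members, 0.30, percentile 99.9). In the whole class MHC class II genes (2 of 6 higher, median -0.06, percentile 43.5) and chemokines and cytokines (9 of 17 higher, median 0.13, percentile 92.4) did not stand apart, with the chemokine gene Cxcl9 at 83.8 and 51.8 CPM. Over all deposited cells the MHC class II list did (0.40, percentile 99.9), as did chemokines with at least 1 UMI per gene (0.14, percentile 99.3). The fibroblast activation list stood apart (7 of 12 higher, median 0.36, percentile 99.8), with Fn1 higher (151 and 267 CPM) and Thbs1 lower (38.5 and 7.89), but its median was -0.27 in the capillary cluster alone. Recruited monocyte genes were higher in 6 of 9 (median 0.49, percentile 99.9), with S100a6 at 334 and 731 CPM, whereas Lyz2, the macrophage lysozyme (53.2 and 131 CPM), was at most 0.569% of its level in the highest class. As a mean over members this list did not stand apart (0.17, percentile 93.8). Ribosomal protein genes were lower in 46 of 81 (median -0.08, percentile 0.21).

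B cell-like cells, 107 in wild type and 297 in AC8, had higher levels of MHC class II genes in AC8, 11 of 11 measured (median log2 ratio 0.39, percentile 99.8). H2-Eb1, a chain of the antigen-presenting complex, stood at 3225 and 4523 CPM and Ctss at 387 and 600 CPM, while the ratios of H2-Oa (232 and 341) and Ciita (106 and 156) had counting intervals that included 1. With at least 100 UMIs per gene the list did not stand apart (0.26, percentile 87.4). Cyclic AMP and CREB targets were higher in 14 of 16 (median 0.27, percentile 98.9), with the orphan receptor gene Nr4a1 (1831 and 2987 CPM) and the stress-induced factor gene Atf3 (134 and 246). That call ended without doublet removal (0.03, percentile 64.3), with at least 1 or at least 100 UMIs per gene (percentiles 94.8 and 94.5) and without the members shared with the stress list (percentile 96.9). Without doublet removal the log2 ratio of Atf3 turned to -0.34. NF-kB targets (13 of 22 higher, median 0.14, percentile 89.5), type I interferon response genes (2 of 11 higher, median -0.29, percentile 11.3) and chemokines and cytokines (4 of 5 higher, median 0.21, percentile 72.6) did not stand apart, and fibroblast activation had fewer than 5 measured members. The named genes were Ccnb1ip1 (35.2 and 195 CPM), Ech1, an enzyme of fatty acid oxidation (28.2 and 108), Cnpy3, a chaperone of Toll-like receptors (35.2 and 110), and Ppp2r1a, a scaffold subunit of protein phosphatase (49.3 and 146), all higher. Golga4 (183 and 38.5), Ash1l (197 and 56.4), Lyst (134 and 41.0) and Ccl21a were lower. The 103 wild-type UMIs of Ccl21a, a chemokine of lymphatic endothelium, lay in 1 cell. Angiogenesis genes were lower in 7 of 7 (median -0.85, percentile 0.15), but on few UMIs of genes typical of endothelium, such as Kdr with 14 and 6, at most 6.60% of its level in the highest class, so this is not read as B cell expression. Mitochondrially encoded (median -0.24, percentile 1.23) and ribosomal protein genes (median -0.06, percentile 0.00) were lower too, the former not apart under 4 other settings (percentiles 2.75 to 3.84).

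**Figure D4:**
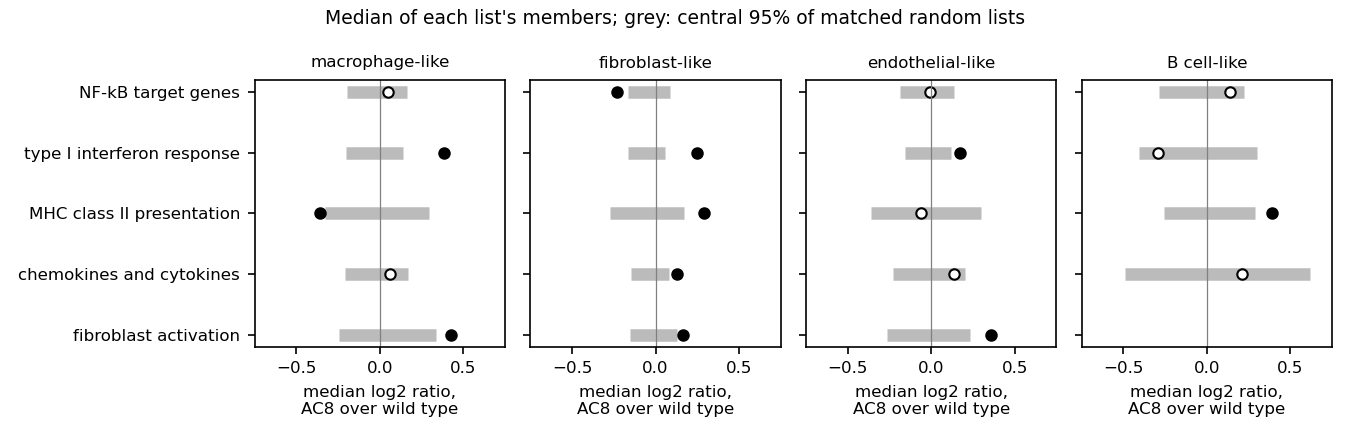
Median log2 ratio of AC8 over wild type (horizontal axis) of the 5 main gene lists in each class compared, with the central 95% of 10000 matched random lists as grey bars and filled points for lists outside them. The type I interferon medians of 0.25, 0.39 and 0.17 in fibroblast-like, macrophage-like and endothelial-like cells lay above their bars, and that of B cell-like cells, -0.29, lay inside.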

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

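The comparison of the macrophage genes with other classes, the clustering without those genes, the count of interferon genes that rose in both classes, and the hemoglobin ratio with its split by class were chosen only after the results they bear on had been seen.

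In AC8 macrophage-like cells, the 8 genes named by rule for the highest ratios, including Gpnmb, Spp1 and Lgals3, had a median log2 ratio of 2.45. Each was at least 2-fold higher, and they are not a count of all such genes. Free RNA, which reaches every droplet, was argued against, since the 8 genes stood at a median of 39.8 times their highest level in fibroblast-like, endothelial-like or B cell-like cells of that library, with the exception of Cd9 (0.449 times), for which it stays open. Thinning every cell to 1000 UMIs left the median at 2.34, so a larger weight of deeper cells in the sums accounted for little of it. The ratios were already scaled to each class's total, and thinning came after filtering, clustering and naming. It could not decide whether the higher UMI count per AC8 cell affected which cells were kept or named. A larger share of AC8 cells in 1 cluster may account for part of the rise: without the cluster found with these genes left out, which held 2.34% of wild-type and 17.0% of AC8 macrophage-like cells, the median was 1.50 (genes from 1.12 to 2.62), between the bounds written for either outcome, while without the original cluster, which these genes helped to define, it was 1.01. Genotype and the preparation of the 2 pools cannot be told apart for that cluster, and a true increase of such macrophages with AC8 remains an untested hypothesis.

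Type I interferon response genes were higher in AC8 macrophage-like, fibroblast-like and endothelial-like cells, though not in the arterial endothelial cluster (-0.22). Free RNA from a single source would add its genes in 1 ratio to every class, but of 38 members the change in CPM was larger in fibroblast-like cells for 8 and in macrophage-like cells for 7 beyond counting error. Among the 21 members that rose in both classes these numbers were 3, including Ifi27l2a and Ifitm3, and 5, including Irf7 and Bst2, which argues against it. Gene length was argued against as the whole cause, since the lowest percentile among the 3 classes was 98.1 against random lists matched on length. A response to AC8 in the heart may be behind it, as a hypothesis drawn from these 2 libraries and not tested. Differences between the pools in infection, housing or handling were not tested either.

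The B cell-like share of leukocytes was 10.1 points higher in AC8. Raising the AC8 minimum by the ratio of the libraries' median UMIs, over all deposited cells, left the difference at 4.59 points (1.29 to 7.87), which was to count against the shared UMI minimum as a cause. That bound proved a poor guide, because the same scaling from a minimum of 1000 UMIs gave -4.85 points (-7.55 to -2.21), so the minimum could account for the direction and the explanation stays open. More blood left in the AC8 hearts stays open too, because hemoglobin, 487 CPM in wild type and 140 CPM in AC8 (ratio 0.287, 0.271 to 0.304), lay almost wholly outside the leukocytes, which held 5.85% and 1.74% of it. It was lower in AC8 in 9 of 10 classes, but it follows red cells, whose lysis is not described, and not blood leukocytes, and whether AC8 hearts held more B cells was not tested.

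MHC class II genes had a median log2 ratio of -0.36 in macrophage-like, 0.29 in fibroblast-like and 0.39 in B cell-like cells. The fibroblast-like rise was not seen in every cluster, and the B cell-like list did not stand apart with at least 100 UMIs per gene. In fibroblast-like cells H2-Ab1 and H2-Eb1 stood far below their level in the highest class, so free RNA of other classes is not excluded there. Cyclic AMP and CREB targets were lower in fibroblast-like (-0.36) and higher in B cell-like cells (0.27), the latter not apart under 4 other settings (percentiles 64.3 to 96.9). The difference between classes was not tested in either case. Myh6, the cardiac myosin heavy chain of a cell type outside the sort, stood at 7.11 CPM in AC8 (5.52 to 9.02) and 3.21 CPM in wild type (2.06 to 4.77), whereas cardiac troponin Tnnt2 stood at 20.2 and 26.5 CPM.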

How the results depend on the processing

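Results for all deposited cells, length-matched lists, macrophage-like cells without 1 cluster, the capillary cluster alone and another seed were chosen only after the data had been seen. No paired analysis was possible because each genotype had 1 library. Of 2443 values of 241 gene results under the alternatives, 2436 were not reversed, and 140 of these moved beyond their counting interval. A gene whose main interval included 1 was not counted as reversed. Of 268 values of 19 main list results, 244 kept their side of the percentile limits. A main list that did not stand apart could change sign within these, as NF-kB targets did in macrophage-like cells (0.05, but -0.07 without the Spp1 and Gpnmb cluster). Of 431 values of 30 other list results 383 kept direction and side, the rest losing their place apart. The losses were most frequent for venous and endocardial genes (8 settings) and collagens (6) in macrophage-like cells and for collagens (6) and oxidative stress genes (6) in endothelial-like cells. Angiogenesis genes lost their place in 3 settings each in fibroblast-like and macrophage-like cells and in 1 in B cell-like cells, and neutrophil genes in macrophage-like cells in 3. Of 87 values of 9 share results, 74 stayed within counting error. The interferon medians ranged from 0.12 to 0.40 in fibroblast-like, 0.18 to 0.43 in macrophage-like and 0.13 to 0.31 in endothelial-like cells and stood apart throughout. Unless stated, the cause of a change was not tested.

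Share differences, in points, moved as follows. With at least 2000 UMIs and 1000 genes, macrophage-like reversed to 5.23, B cell-like to -0.67, and T cell-like was -6.38. Among all deposited cells with at least 2000 UMIs, however, B cell-like was 0.44 (-1.36 to 1.74). With at least 2000 UMIs and 1000 genes, no NK cell-like or neutrophil-like class was found. With each library clustered alone, dendritic was 9.26 and T cell-like 8.10, since wild type formed no dendritic or T cell-like cluster there. In that setting macrophage-like was -18.7 and NK cell-like -6.20. NK cell-like was -4.25 with 1000 variable genes. Over all deposited cells, macrophage-like was -2.12, neutrophil-like -1.90, B cell-like 5.60, fibroblast-like 2.89 and mural-like -2.21.

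Median log2 ratios of the main lists moved as follows. In fibroblast-like cells NF-kB targets were -0.0733 without doublet removal, -0.0884 with at least 1 UMI per gene and -0.16 over all deposited cells. Chemokines there were 0.0596 with a mitochondrial limit of 5%, 0.0310 with at least 1 UMI, -0.0140 (reversed) with at least 100 UMIs, and 0.13, just under the limit, when matched on length. In macrophage-like cells fibroblast activation was 0.24 at Leiden resolution 1.6, 0.00141 without doublet removal, 0.0232 with at least 1 UMI, 0.26 without the Spp1 and Gpnmb cluster and -0.13 (reversed) over all deposited cells. The mean over members there gave -0.26 for MHC class II and 0.30 for chemokines, which then stood apart. In endothelial-like cells fibroblast activation was -0.000749 (reversed) with at least 1 UMI, 0.12 as a mean, 0.11 over all deposited cells and -0.27 (reversed) in the capillary cluster alone. Chemokines there stood apart at 0.14 with at least 1 UMI and MHC class II at 0.40 over all deposited cells. In B cell-like cells the interferon list stood apart at -0.39 both without doublet removal and with a mitochondrial limit of 20%. NF-kB targets stood apart at 0.27 with at least 1 UMI, and MHC class II no longer did at 0.26 with at least 100 UMIs.

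Single genes that reversed were Ppbp (log2 ratio -0.0226), Vegfa (-0.16) and Hp (-0.0613) in macrophage-like cells without the Spp1 and Gpnmb cluster. Over all deposited cells they were Col15a1 (0.0639) and Eln (0.0697) in endothelial-like cells and Cxcl12 (0.20) in B cell-like cells. Without doublet removal it was Atf3 (-0.34) in B cell-like cells.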

Other observations

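Glycolysis genes were higher in AC8 in 3 classes and nuclear genes of oxidative phosphorylation in 2. The hypoxia and glycolysis list was higher in macrophage-like cells (21 of 25 members, median log2 ratio 0.37, percentile 100), with the glycolytic enzymes Pkm (190 and 524 CPM), Pgam1 (91.9 and 255) and Pgk1 (46.3 and 130). Without the Spp1 and Gpnmb cluster the list kept its place (0.40, percentile 100), while these genes stood closer, at 172 and 325 CPM for Pkm, 80.5 and 127 for Pgam1 and 40.2 and 66.8 for Pgk1. It was higher in endothelial-like cells (17 of 25, 0.26, percentile 100), with Tpi1 (75.9 and 144) and the mitophagy gene Bnip3 (71.4 and 149). In fibroblast-like cells it was higher in 18 of 28 (0.17, percentile 99.8), with the lactate dehydrogenase gene Ldha (298 and 443). Nuclear genes of oxidative phosphorylation were higher in 55 of 57 in macrophage-like cells (0.37, percentile 100), such as Cox5a (167 and 304 CPM), and in 51 of 57 in fibroblast-like cells (0.21, percentile 100). They did not stand apart in endothelial-like cells (0.06, percentile 87.5), and in B cell-like cells neither list did (percentiles 31.1 and 50.6). Mitochondrially encoded genes were lower in macrophage-like and fibroblast-like cells. In endothelial-like cells the oxidative stress list was higher in 15 of 18 (0.18, percentile 97.7), with Prdx6 (54.4 and 95.8 CPM), but it did not stand apart under 6 other settings (percentiles 93.3 to 97.4).

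The interferon list was also taken within single clusters. It was higher in AC8 in all 4 fibroblast-like clusters measured (medians 0.38, 0.26, 0.26 and 0.15), in both macrophage-like clusters measured (0.35 and 0.27) and in the capillary endothelial cluster (0.31), each at percentile 97.7 or above. In the arterial endothelial cluster led by Stmn2, Clu and Sox17, with 119 and 144 cells, it was -0.22 (percentile 10.8). The difference between the endothelial clusters was not tested.

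Some genes differed between the libraries in every class compared. Over all kept cells, Ccnb1ip1 stood at 38.5 CPM in wild type and 120 in AC8, and the ribosomal protein genes Rpl10 (1589 and 690 CPM) and Rps12 (1149 and 454) were lower in AC8, a larger fall than in the whole list of ribosomal protein genes, whose median log2 ratios were -0.01 in fibroblast-like, -0.17 in macrophage-like, -0.08 in endothelial-like and -0.06 in B cell-like cells. These 3 genes were picked after their values were seen. Hemoglobin RNA was lower in AC8 as well, with Hbb-bs at 214 and 50.5 CPM.

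Across genes, which are not independent replicates, longer genes had lower ratios. The Spearman correlation of gene length with the log2 ratio was -0.39 in fibroblast-like, -0.36 in macrophage-like, -0.30 in endothelial-like and -0.16 in B cell-like cells. In fibroblast-like cells the median log2 ratio was 0.11 for the shortest 20% of genes, up to 8766 bp, and -0.20 for the longest 20%, from 74879 bp.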
